A study of Homo sapiens with 16 samples.

How the data were processed

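Poly-A RNA was sequenced from A375 MA2-Luc melanoma, an established human cell line that was injected behind the eye of NSG mice, an immunodeficient strain. Per the labels, 16 libraries formed 4 groups of 4: high fat diet without inhibitors, high fat diet with inhibitors, ketogenic diet without inhibitors and ketogenic diet with inhibitors. The labels call every sample a lung metastasis, while the series' design text also speaks of a cultured line, so whether cells were cultured between the lung and the extraction is not settled. They do not name the inhibitors or their doses, and do not say whether each replicate came from its own mouse. P-values then measure the spread between these libraries.

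The deposited file holds RSEM expected counts (estimated counts) for 26475 gene symbols in 16 columns, not scaled for depth. The submitters' processing notes name Bowtie2 2.1.0, RSEM 1.2.15 and build hg38, with no role or order. The annotation, the strand setting and any removal of mouse reads are not given in the sources used here. Of the values, 13.0% were not whole numbers, and they were rounded before the tests. Reads were not analysed here. Totals ran from 37.1 to 77.3 M estimated counts (M, mega) per library, and 32.2 to 51.2 M after the ribosomal RNA genes were set aside.

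Genes were filtered by edgeR's filterByExpr with the 4 groups, which left 16012. Counts were scaled with TMM and fitted in edgeR 4.0.16 (R 4.3.3) with robust quasi-likelihood dispersions, all 16 libraries in one model of group means. There were 5 comparisons: inhibitors against none on each diet, ketogenic against high fat diet without and with inhibitors, and the difference of the inhibitor effect between diets (ketogenic minus high fat). Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05 and no fold minimum. The common biological coefficient of variation was 0.228. Fold changes are edgeR log2 values with their standard error (SE), each over 4 libraries per group. A median fold of called genes is also on the log2 scale, with each gene signed by its direction in the main fit. The SE beside it is the median SE of those genes, not the SE of the median. Levels are CPM on TMM-scaled library sizes, given as means of 4.

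Gene lists were fixed in advance, 35 in all. Of 668 entries, 645 were in the table, and the list of mitochondrially encoded genes had no tested member. The other 34 were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01), adjusted over the lists of a comparison, and again with a correlation estimated per list. Members past the test are counted over all genes tested and, where said, adjusted over the list alone. The share of ribosomal RNA was compared with a two-sided exact permutation test of the log2 share.

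The text takes its genes from a rule written in advance. For each comparison it named the 5 genes with the highest and the 5 with the lowest log2 fold change among those past the test with a mean of at least 5 CPM in the higher group and no overlap between the groups. For the difference of effects, 5 CPM in any group sufficed and overlap was allowed. It further named 2 members of each of 9 core lists by smallest p, targets such as BRAF, MAP2K1, MAP2K2 and MAPK3, and 3 members of any other list past its test. The rule took 52, 36, 58, 42 and 59 genes in the 5 comparisons. Some genes that the rule took are not reported here, and the other genes of its first part are all given in the text. The rest are a selection made after their values were seen, as are DUSP6, SPRY4, LCP1, AREG, IL1B, CXCL8, IFIT2, IFIT3, MX1, AKR1C1 and AKR1C2 where the rule did not take them. Coordinates are 1-based GENCODE 29 positions on the same build, and 90 of 94 genes had a single location.

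The procedure was tested on simulated counts with 200 changed genes, drawn from each gene's mean over all libraries, the real library sizes and the estimated dispersions. The test was written and run after the main fit had been run on the real counts, not before it. At a 2-fold change it recovered 71% of genes for the inhibitors on the high fat diet, 79% on the ketogenic diet, 77% for the diets without inhibitors, 78% with them, and 44% for the difference of effects. At a 1.5-fold change recovery was 42%, 44%, 38%, 24% and 4% in that order. Unchanged genes called were 7, 10, 5, 6 and 6 in that order. With no gene list raised, 1 list was called for the diets without inhibitors, 0 with them and 1 for the difference of effects. Genes were drawn independently, so shifts of many genes together in a library were not simulated. False calls in the real data, above all of lists, may thus be more frequent. In some of the alternative fits, most of all the one with no low-count filter, some genes with a p value of 1 have no SE; no gene of the main fit is affected.

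Alternatives were DESeq2 1.42.0, RLE factors, library size alone, other low-count filters, a fit of only the libraries compared, limma voom with quality weights, a fold minimum of 1.5, the replicate number as a block, each library left out in turn, fry for lists, and 5 settings chosen after seeing the data. These removed the ribosomal RNA genes, used the ribosomal RNA share as a covariate, left out the 3 libraries with over 30% ribosomal RNA or the 4 least like their own group, or used an offset for transcript length and GC content.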

Results

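The 16 libraries held poly-A RNA of A375 MA2-Luc melanoma from the lungs of immunodeficient mice on a high fat or a ketogenic diet. The mice had no inhibitors (called untreated here) or inhibitors given by mouth 3 times a week for 5 weeks. No gavage schedule is given for the groups without inhibitors. Whether they received a vehicle is thus open, and gavage cannot be told apart from the inhibitors. Each of the 4 combinations of diet and treatment had 4 libraries. High fat libraries without inhibitors held 63.8, 56.4, 64.5 and 58.1 M estimated counts (M, mega), and those with inhibitors 52.0, 58.1, 59.2 and 59.2 M. Ketogenic libraries without inhibitors held 68.7, 77.3, 50.05 and 38.6 M, and those with inhibitors 52.5, 49.0, 37.1 and 52.3 M. Ribosomal RNA took 32.7% ± 13.5 of the counts (SD, n = 4) in untreated high fat libraries, 17.3% ± 2.20 with inhibitors, 23.7% ± 7.97 in untreated ketogenic libraries and 7.08% ± 2.00 with inhibitors. The log2 share was lower with inhibitors on the high fat diet (-0.83) and on the ketogenic diet (-1.74), each with an exact permutation p of 0.0286 (adjusted 0.0381), the smallest that 70 assignments can give. Between diets it differed by -1.34 with inhibitors (exact permutation p = 0.0286, adjusted 0.0381) and by -0.44 without them (exact permutation p = 0.314).

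**Figure D1:**
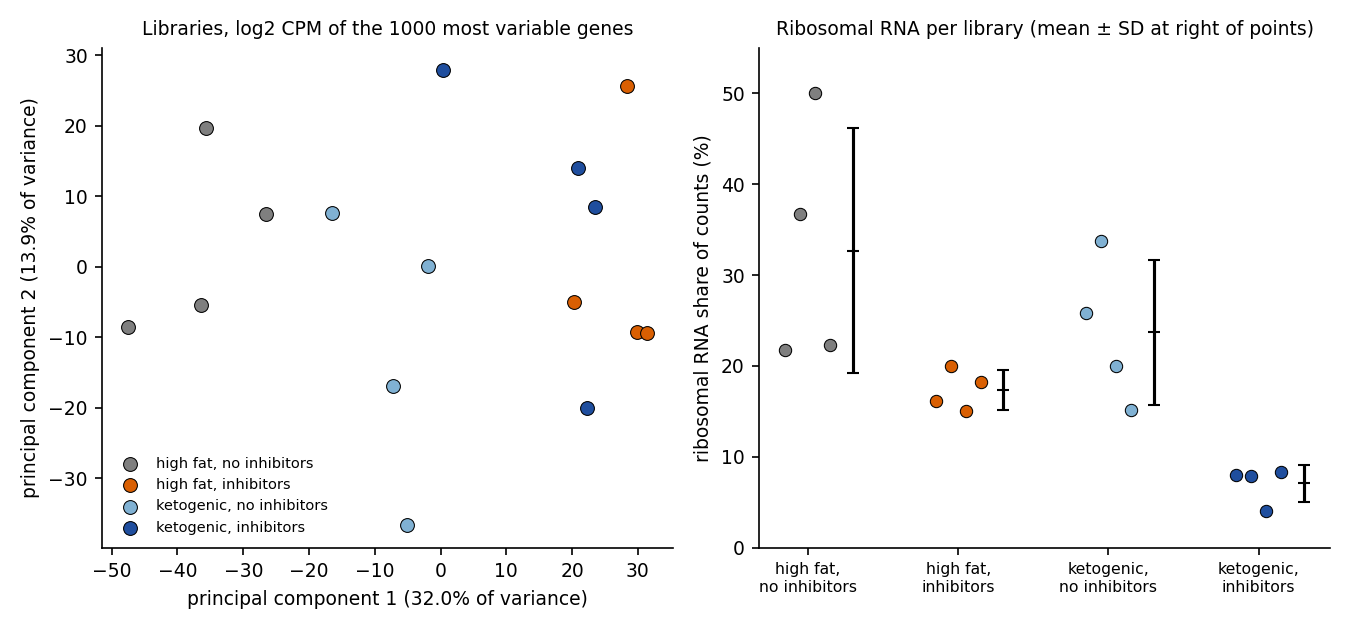
Left, the 16 libraries on principal components 1 and 2 of log2 CPM, coloured by group; right, the ribosomal RNA share of each library in percent, with mean and SD. The first component holds 32.0% of the variance, and the untreated high fat libraries lie at its low end (mean -36.5) and the high fat libraries with inhibitors at its high end (mean 27.4).

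The first comparison asked which genes differ between metastases that grew under the inhibitors and untreated metastases on the high fat diet. Among the strongest rises were those of FMOD, a collagen-binding proteoglycan, FGL2, a secreted fibrinogen-like protein, TTR, a carrier of thyroid hormone and retinol, and NTS, the precursor of neurotensin. FMOD (chromosome 1, 203340628 to 203351758) went from 0.138 to 5.38 CPM, a 39.9-fold rise (log2 5.32, SE 0.48, n = 4 per group). FGL2 (chromosome 7, 77193371 to 77199848) went from 2.17 to 81.1 CPM (log2 5.21, SE 0.62), TTR (chromosome 18, 31557010 to 31599021) from 1.31 to 42.8 CPM (log2 5.04, SE 0.54) and NTS from 0.224 to 5.39 CPM (log2 4.60, SE 1.08). The strongest falls were in LDB2, a LIM-domain-binding cofactor (chromosome 4, 16501541 to 16898809; log2 -4.27, SE 0.56, from 13.5 to 0.703 CPM), NCAM2, a neural cell adhesion molecule (log2 -3.84, SE 0.71), the non-coding RNA LINC00663 (log2 -3.71, SE 0.50), the adaptor STAC (log2 -3.46, SE 0.28) and FRAS1, a basement membrane protein (log2 -3.41, SE 0.47). These 9 genes are among the strongest of those that the rule allows, with at least 5 CPM in the higher group and no overlap between the groups. Their edgeR quasi-likelihood adjusted p lay between 2.30e-06 (STAC) and 0.00406 (NTS).

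On the high fat diet 19 of 20 S phase genes rose and 0 fell (19 rose adjusted over the list alone), with a median log2 fold change of 1.39. The list had an adjusted p of 1.61e-10 in camera with the preset correlation and of 0.666 with an estimated one. Among them CCNE2, the cyclin E of S phase entry, rose by 2.71 (SE 0.31) and the transcription factor E2F1 by 1.74 (SE 0.22). Of 20 genes of G2 and mitosis 8 rose (10 adjusted over the list alone), with a median of 0.89, and the mitotic kinase CDK1 went from 42.7 to 100 CPM (log2 1.23, SE 0.32). Untreated replicate 4 stood apart in mitotic genes, with CDK1 at 15.1 CPM (others 48.7 to 56.8), the kinase PLK1 at 7.07 (57.4 to 65.4) and the topoisomerase TOP2A at 34.3 (261 to 297). Without that library the median of the list was 0.58 and 10 genes rose, and without the fourth library with inhibitors 5 rose. Of 21 glycolysis genes 10 rose and 4 fell (11 and 4 adjusted over the list alone), among them the glucose transporter SLC2A1 (log2 0.98, SE 0.10) and the pyruvate kinase PKM (log2 1.40, SE 0.18, from 654 to 1729 CPM). Of 26 nuclear genes of oxidative phosphorylation 12 rose and 1 fell (13 and 1 adjusted over the list alone), with NDUFA4 at 0.80 (SE 0.16). Of 16 genes of the unfolded protein response 9 rose and 0 fell, such as EDEM1, which directs misfolded proteins to degradation (log2 1.10, SE 0.18), and the chaperone CALR (log2 0.73, SE 0.14). The list of immediate early and heat shock genes, which also marks tissue handling, had 6 of 19 higher, among them JUN (from 9.87 to 53.3 CPM, log2 2.43, SE 0.33). Ribosomal proteins went the other way, with 17 of 24 lower (19 adjusted over the list alone), for example RPL4 (log2 -0.64, SE 0.15), and 9 to 16 lower with single libraries left out. The counts for the unfolded protein response and for handling were the same adjusted over the list alone. The ribosomal RNA share was 17.3% in the libraries with inhibitors against 32.7%.

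The inhibitors are not named in the labels, and the MAPK pathway, a common drug target in melanoma, was among the lists. Of 20 genes driven by MAPK signalling 4 rose and 4 fell: the phosphatase DUSP6 rose (log2 0.68, SE 0.22), and the inhibitor SPRY4 (log2 -0.63, SE 0.18) and the receptor EPHA2 (log2 -1.09, SE 0.24) fell. Of 12 drug targets and MAPK core genes 7 rose and 2 fell. The kinase BRAF fell by 0.66 (SE 0.11) and MAP2K1 rose by 0.25 (SE 0.09), while MAP2K2 (log2 -0.06, SE 0.11) and MAPK3 (log2 0.10, SE 0.11) did not pass. Leaving out single libraries ended the call of MAP2K1 in 5 of 8 cases (adjusted p up to 0.0923, without untreated replicate 3) and of DUSP6 in 3 (up to 0.0642, without untreated replicate 1). Without untreated replicate 4 DUSP6 was at 1.05. Of 20 receptor kinases and ligands 4 rose and 6 fell, among them KDR, the main VEGF receptor (from 21.8 to 75.1 CPM, log2 1.78, SE 0.24). Melanocyte genes had 3 of 16 higher, one of them BCL2A1, a survival factor (log2 1.48, SE 0.18), and 1 lower. In the list of the dedifferentiated melanoma state 7 of 20 rose and 2 fell, including ZEB1, a repressor of epithelial genes (log2 -1.16, SE 0.15). In the matrix list 2 of 24 rose and 5 fell, including the collagen chain COL5A1 (log2 -1.27, SE 0.14). Of genes that handle fuel, 3 of 11 for ketone bodies and 6 of 24 for fatty acid oxidation rose, and 2 and 5 fell. For fatty acid synthesis 1 of 14 rose and 4 fell, and for cholesterol synthesis 5 of 21 and 3. Without untreated replicate 4, 6 receptor kinases and ligands rose and 4 fell, 5 matrix genes rose and 9 genes of fatty acid synthesis fell. Over the single libraries left out 1 to 3 ketone body genes rose and 1 to 2 fell, and 3 to 6 genes of cholesterol synthesis rose and 0 to 5 fell. Of the MAPK core 1 to 2 fell, as did 1 to 2 melanocyte genes, 1 to 3 dedifferentiation genes and 3 to 5 matrix genes. Erythroid and plasma markers rose in 5 of 5 tested members, among them TTR and the protease inhibitor SERPINA1 (log2 0.67, SE 0.17). Markers of leukocytes rose in 2 of 7, of macrophages and neutrophils in 1 of 7 (1 fell) and of endothelium in 2 of 9. As single libraries were left out 3 to 5 erythroid and plasma markers rose (3 without replicate 1 with inhibitors), 1 to 3 of endothelium rose (1 without replicate 2 with inhibitors) and 0 to 1 of macrophages fell. Markers of fibroblasts rose in 1 of 12 (4 fell), those of lung epithelium in 0 of 7 (3 fell) and of adipocytes in 0 of 5 (1 fell). The next levels cover all listed genes in the data and are set in part by genes too low to test (7 of 17 leukocyte, 7 of 22 lung epithelial and 5 of 14 erythroid and plasma genes were tested). The median member stayed at or under 0.104 CPM in every group for leukocytes, 0.154 for macrophages and neutrophils, 0.472 for endothelium, 2.22 for fibroblasts, 0.0534 for lung epithelium, 0.0844 for erythroid and plasma markers and 0.145 for adipocytes. The most abundant member of each, averaged over all libraries, was CORO1A (4.23 CPM), CD68 (45.3), KDR (41.3), FBLN1 (34.4), KRT18 (128), TTR (21.3) and LPL (147).

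In all, 6771 of 16012 genes passed the edgeR quasi-likelihood test, 3295 higher and 3476 lower, and 1987 of them changed over 2-fold. The groups did not overlap in 7160 of all genes tested (44.7%), where chance gives 2.86%. Camera put 8 of 34 lists past an adjusted p of 0.05, those for S phase (1.61e-10), G2 and mitosis (9.81e-05), glycolysis (0.0169), oxidative phosphorylation (0.00576), the unfolded protein response (0.0053), handling (0.0161), erythroid and plasma markers (0.0493) and ribosomal proteins (9.81e-05), and each had an adjusted p of 0.666 with an estimated correlation. Without untreated replicate 4 the count of lists was 5. Without the 3 libraries with over 30% ribosomal RNA the count of genes was 3858, and against a 1.5-fold minimum 1180. FMOD rested on 27 counts over the 4 untreated libraries, so its fold is coarse.

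**Figure D2:**
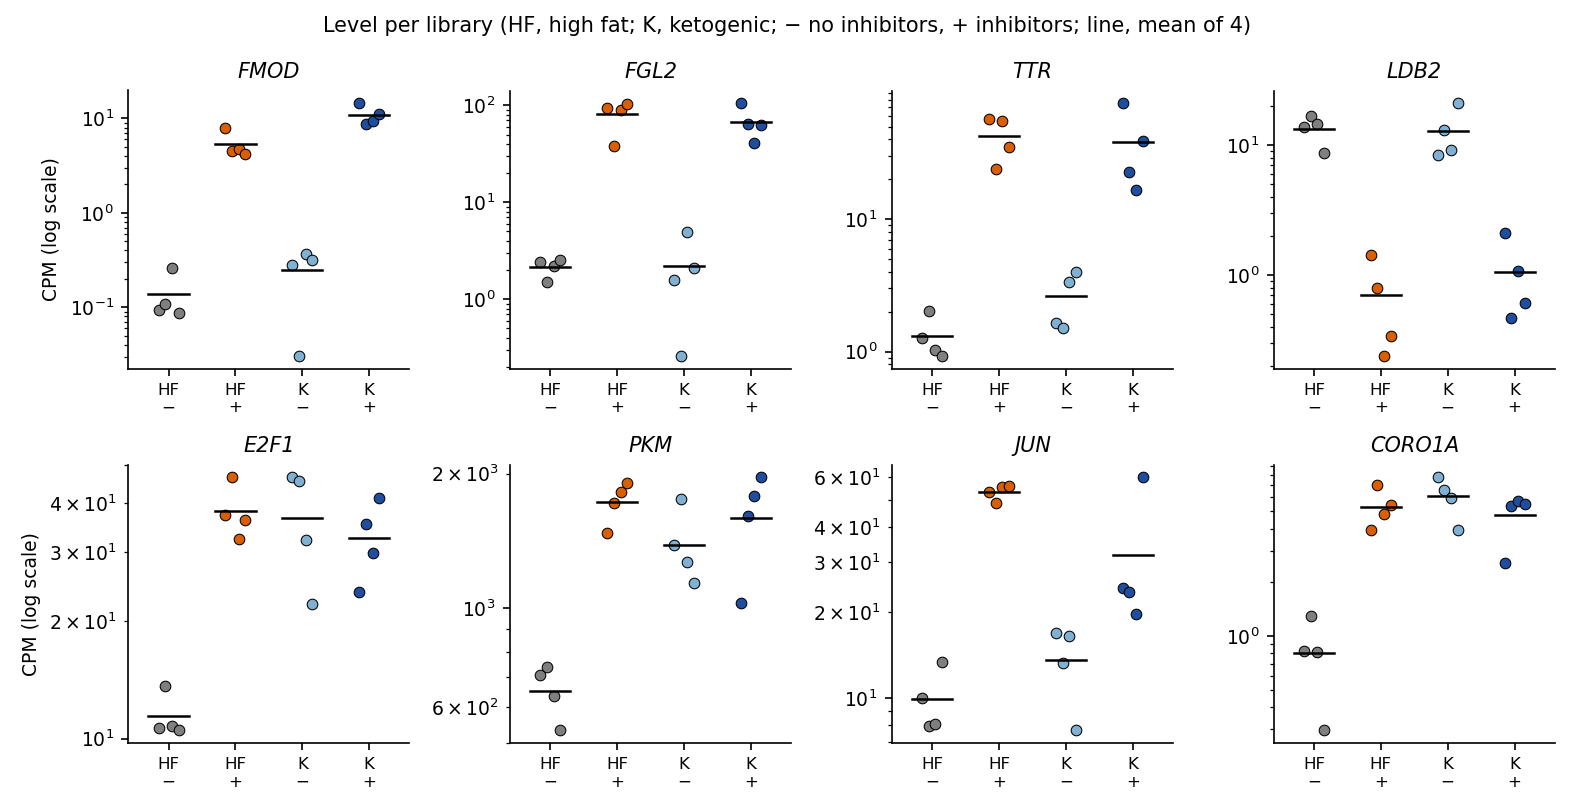
CPM of 8 genes in each library on log axes, by diet (HF, high fat; K, ketogenic) and treatment, with the mean of 4 as a line. FMOD, FGL2 and TTR were higher and LDB2 lower in every library with inhibitors than in every library without on either diet, whereas E2F1 (mean 11.4 CPM), PKM (654 CPM) and CORO1A (0.808 CPM) were lowest in untreated high fat libraries.

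On the ketogenic diet the same question gave far fewer genes, with several of the same names at the top. FMOD rose from 0.249 to 10.98 CPM (log2 5.49, SE 0.46, n = 4 per group; edgeR quasi-likelihood adjusted p = 1.84e-05), FGL2 from 2.22 to 68.2 CPM (log2 4.96, SE 0.61) and TTR by 3.90 (SE 0.51). EFS, a docking protein of Src-family signalling, rose by 3.32 (SE 0.59). LDB2 fell by 3.60 (SE 0.54), CYP24A1, the enzyme that degrades active vitamin D, by 3.25 (SE 0.76), and the secreted pentraxin NPTX2 by 2.56 (SE 0.55). The ribosomal RNA genes RNA45S5 (log2 -2.08, SE 0.29) and RNA28S5 (log2 -2.06, SE 0.35) were also among the strongest falls, in poly-A selected libraries whose ribosomal share was 7.08% against 23.7%. Leaving out single libraries ended the call of CYP24A1 in 6 of 8 cases (log2 -2.22 and adjusted p = 0.122 without untreated replicate 2), of NPTX2 in 3 (up to 0.0832) and of EFS in 1 (0.0511, without untreated replicate 1).

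With inhibitors on the ketogenic diet camera gave the lists of the dedifferentiated melanoma state (adjusted p = 0.000552) and of the matrix (0.00462) as lower, but neither with an estimated correlation (0.276 each). Of 20 dedifferentiation genes 0 rose and 1 fell, the protease-activated receptor F2RL1 (log2 -1.17, SE 0.24), with 1 higher and 9 lower adjusted over the list alone. The receptor EGFR (log2 -1.03, SE 0.29) and the matrix protein TGFBI (log2 -1.06, SE 0.26) of this list did not pass over all genes, and its median was -0.42. Of 24 matrix genes 0 rose and 4 fell (1 and 5 adjusted over the list alone): COL4A1, COL4A2, COL5A1 (log2 -1.08, SE 0.14) and the integrin ITGA3 (log2 -0.79, SE 0.18); the list's median of -0.21 became 0.06 on library size alone, and 1 to 3 fell with single libraries left out. Of dedifferentiation genes 0 to 3 fell, with the 3 in the case without the second library with inhibitors. Of 14 genes of fatty acid synthesis none passed, with the carboxylase ACACB at -0.70 (SE 0.22), the desaturase FADS1 at -0.35 (SE 0.12) and a median of -0.24 that became 0.03 on library size alone. That scaling counts ribosomal RNA in the library size and moved the median of all genes to 0.28. The medians of 0.06 and 0.03 still lay below it. Of 20 genes driven by MAPK signalling 0 passed (EPHA2 -0.63, SE 0.24), and neither did BRAF (log2 -0.44, SE 0.11). SLC24A5, an ion exchanger of pigment granules, rose from 26 counts over 4 untreated libraries to 1074 (log2 5.26, SE 0.96) and 1 untreated library had none. Among markers of other cells, 1 of 7 leukocyte genes rose (LCP1, an actin-bundling protein, log2 2.22, SE 0.45), as did 1 of 5 erythroid and plasma genes (TTR), and the other 5 marker lists had none past the test. Leaving out single libraries ended the call of ITGA3 in 5 of 8 cases (adjusted p up to 0.0964), of LCP1 in 4 (0.0772), of F2RL1 in 2 (0.0651) and of SLC24A5 in 1 (0.0610, without untreated replicate 1).

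The edgeR quasi-likelihood test passed 279 genes, 137 higher and 142 lower, against 2995 at an unadjusted p under 0.05. Camera passed 3 lists, the third that of fatty acid synthesis (adjusted p = 0.00753, and 0.726 with an estimated correlation). It passed 6 without the fourth untreated library and 5, 5 and 7 without the first, the second and the third with inhibitors. The count of genes is sensitive to single libraries, from 88 without the first untreated library to 437 without the first one with inhibitors. Without the 4 libraries least like their group, among them the first and the fourth with inhibitors on this diet, 1029 genes passed. With the ribosomal RNA share as a covariate 0 genes passed edgeR. The median log2 fold of the 279 genes went from 0.86 (SE 0.18) to 0.83 (SE 0.32). The share ran from 4.10 to 8.37% with inhibitors and from 15.2 to 33.7% without, with no overlap. The fit thus parts ribosomal RNA poorly from the inhibitors, and the lost calls do not decide between them. Without the covariate DESeq2 gave 850 and limma voom with quality weights 1456.

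Across 16012 genes the inhibitor effects on the 2 diets correlated with Pearson's r of 0.389 and Spearman's rho of 0.410, over genes, which are not independent replicates. Of the 279 genes of the ketogenic diet 247 had the same sign on the high fat diet, 100 rose on both diets where independent lists would share 28.2, 88 fell on both against 30.8, and 9 went opposite ways. The genes that passed on the high fat diet had a median absolute log2 fold change of 0.68 there and moved by 0.17 in that direction on the ketogenic diet. The genes that passed on the ketogenic diet had a median absolute log2 fold change of 0.86 there and of 0.66 on the high fat diet. Part of the smaller size on the other diet is expected in both cases, since the genes were selected by their change on one.

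**Figure D3:**
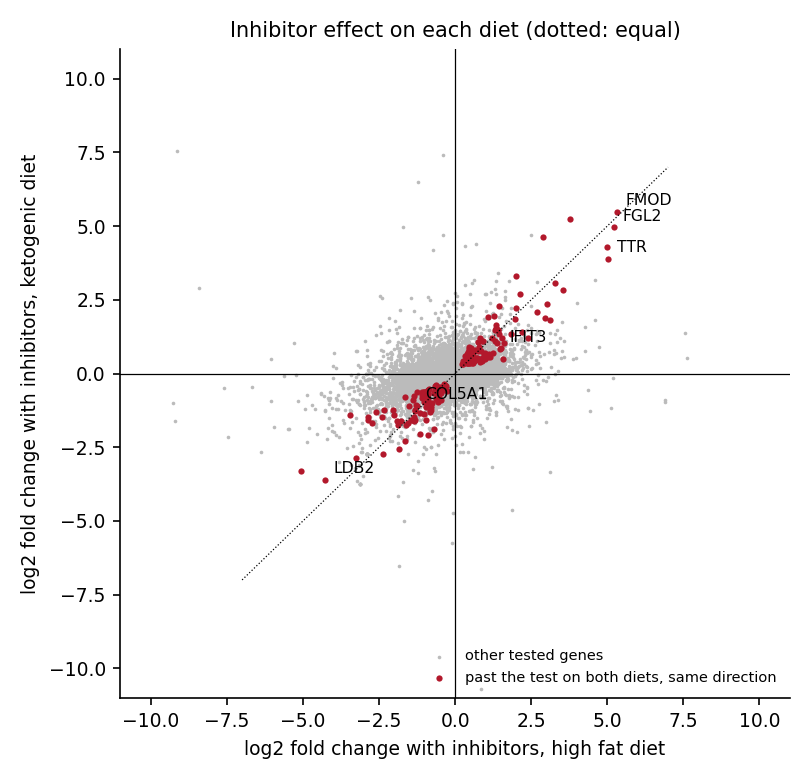
Log2 fold change with inhibitors on the high fat diet (horizontal) against the ketogenic diet (vertical) for each tested gene, with the 188 genes past the test on both diets in the same direction in red. FMOD (5.32 and 5.49) and LDB2 (-4.27 and -3.60) lie near the line of equal change.

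Without inhibitors, the ketogenic diet was compared with the high fat diet to see what the diet alone did. CYP24A1 rose on the ketogenic diet (log2 3.13, SE 0.76, n = 4 per group), as did IL7R, the interleukin-7 receptor (log2 2.92, SE 0.82), CORO1A, an actin-binding protein common in leukocytes (from 0.808 to 6.05 CPM, log2 2.91, SE 0.37; edgeR quasi-likelihood adjusted p = 0.00171), the calcium-binding S100A3 (log2 2.88, SE 0.69) and IGFBP5, which binds insulin-like growth factors (from 11.9 to 73.0 CPM, log2 2.62, SE 0.52). BEST1, a chloride channel (log2 -2.18, SE 0.40), the transcript LOC729732 (log2 -1.99, SE 0.53), the protease PAPPA (log2 -1.93, SE 0.37), C6orf48 (log2 -1.89, SE 0.49), which hosts small nucleolar RNAs, and the adaptor SHC2 (log2 -1.89, SE 0.56) fell. Untreated ketogenic replicate 2 had CYP24A1 at 12.7 CPM (others 1.59 to 3.76), and without it the log2 fold change was 2.101 for CYP24A1 (adjusted p = 0.0698) and 1.89 for S100A3 (0.0629). Without it the calls of IL7R (0.0902), LOC729732 (0.0758), C6orf48 (0.0788) and SHC2 (0.122) ended too. Without untreated high fat replicate 4 BEST1 was at -1.48. Other single libraries also ended calls, in 6 of 8 cases in all for IL7R and SHC2.

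S phase genes rose with the ketogenic diet in 18 of 20 (20 adjusted over the list alone), with a median of 1.25, including E2F1 (log2 1.69, SE 0.22) and the replication helicase subunit MCM5 (log2 1.59, SE 0.25). Of 20 genes of G2 and mitosis 7 rose (16 adjusted over the list alone), with CDK1 at 1.21 (SE 0.32). Untreated high fat replicate 4 lay far below its group in mitotic genes (PLK1 at 7.07 CPM, others 57.4 to 65.4). Without it the median of the list went from 1.03 to 0.73 while 12 genes rose. With other single libraries left out as few as 0 rose. Of 21 glycolysis genes 10 rose and 0 fell, with PKM at 1.08 (SE 0.18) and the lactate dehydrogenase LDHA at 0.71 (SE 0.14), and 4 of 26 genes of oxidative phosphorylation rose. Of 16 genes of the unfolded protein response 8 rose and 1 fell, with the disulphide isomerase PDIA4 at 0.83 (SE 0.14). Of 20 dedifferentiation genes 5 rose, such as CTGF, a matricellular protein (log2 1.61, SE 0.29), and the intermediate filament NES (log2 0.79, SE 0.16). Of 19 YAP and TGF-beta targets 4 rose and 1 fell, the ligand TGFB2 (log2 -1.66, SE 0.39). Of 16 hypoxia genes 3 rose, as did 3 of 12 drug targets and MAPK core genes, with MAPK3 at 0.43 (SE 0.11), and 3 of 19 handling genes, with the small heat shock protein HSPB1 at 0.99 (SE 0.14). Of the 24 genes of fatty acid oxidation 6 rose and 2 fell, one of these ACSL1, which activates long fatty acids (log2 -0.71, SE 0.11), and of 11 ketone body genes 1 fell, AACS, which activates acetoacetate in the cytosol (log2 -0.47, SE 0.11). Ribosomal proteins fell in 3 of 24 (18 adjusted over the list alone), with RPL10 at -0.50 (SE 0.16). EPHA4 rose by 0.78 (SE 0.24), while the melanin enzyme DCT (log2 -2.99, SE 0.65, from 3.45 to 0.434 CPM) and COL5A1 (log2 -0.60, SE 0.14) fell. Leukocyte markers rose in 2 of 7 (CORO1A and FCER1G), macrophage markers in 1 of 7 and plasma markers in 1 of 5. Fibroblast markers fell in 2 of 12, lung epithelial markers in 1 of 7 and adipocyte markers in 1 of 5, and endothelial markers had none. Adjusted over the list alone, 12 glycolysis genes rose, 7 of oxidative phosphorylation, 9 of the unfolded protein response (1 fell), 6 of dedifferentiation (1 fell), 8 of fatty acid oxidation (2 fell), 4 YAP and TGF-beta targets (1 fell), 4 of hypoxia, 5 of the MAPK core and 6 of handling. With single libraries left out the genes that rose over all genes were 17 to 19 for S phase, 6 to 10 for glycolysis, 5 to 12 for the unfolded protein response, 3 to 9 for dedifferentiation and 3 to 8 for fatty acid oxidation. They were 1 to 5 for oxidative phosphorylation, 2 to 7 for YAP and TGF-beta targets, 1 to 3 for hypoxia, 0 to 4 for the MAPK core and 1 to 6 for handling, and 0 to 9 ribosomal proteins fell. Of leukocyte markers 1 to 2 rose, and of fibroblast markers 0 to 2, of lung epithelium 0 to 1 and of the unfolded protein response 0 to 1 fell. Leaving out single libraries ended the call of RPL10 in 6 of 8 cases (adjusted p up to 0.129), of EPHA4 in 5 (0.119), of CDK1 and MAPK3 in 3 (0.0728 and 0.0800) and of AACS in 1 (0.0528).

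The edgeR quasi-likelihood test passed 2163 genes, 1280 higher and 883 lower, and the groups did not overlap in 25.5% of all genes tested, where chance gives 2.86%. Camera passed 12 of the 34 lists, those with counts above other than ketone bodies and the cell type markers, with adjusted p from 1.24e-15 (S phase) to 0.0472 (hypoxia). With an estimated correlation their adjusted p were 0.331 for S phase, glycolysis, dedifferentiation, fatty acid oxidation, YAP and TGF-beta, and the MAPK core, 0.377 for the unfolded protein response, 0.400 for G2 and mitosis and for handling, 0.496 for oxidative phosphorylation and ribosomal proteins and 0.547 for hypoxia. Without the 3 libraries with over 30% ribosomal RNA 0 genes passed edgeR, with the median fold of the 2163 genes going from 0.62 (SE 0.15) to 0.58 (SE 0.21). With all libraries 4909 had an unadjusted p under 0.05, DESeq2 gave 3091 genes and limma voom with quality weights 6393. Leaving out any of the first 3 untreated ketogenic libraries gave 919, 778 and 1409 genes, and leaving out the third untreated high fat library 1044.

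**Figure D4:**
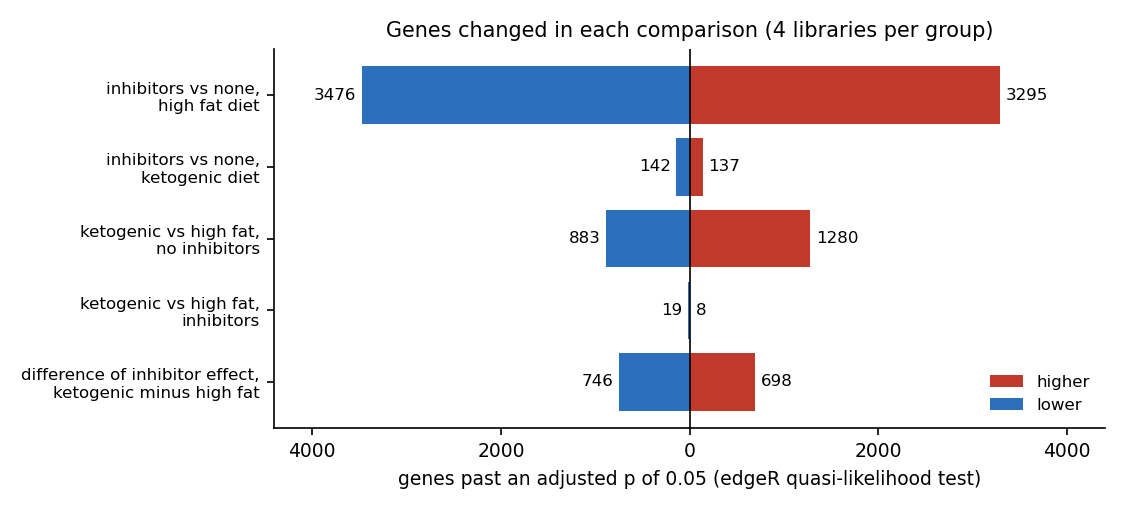
Genes past the edgeR quasi-likelihood test in each of the 5 comparisons, as bars to the right (higher) and to the left (lower). The inhibitor effect on the high fat diet had 3295 higher and 3476 lower, and the diets with inhibitors 8 and 19.

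With inhibitors, the diets differed in few genes. Higher on the ketogenic diet were the antisense transcript EIF3J-AS1 (log2 0.92, SE 0.17, n = 4 per group), whose reads cannot be told from its partner's without strand, the membrane-associated PLEKHB1 (log2 0.87, SE 0.17), the non-coding LINC01138 (log2 0.69, SE 0.13), PCOLCE2, which assists collagen processing (log2 0.68, SE 0.12), and the nucleolar KNOP1 (log2 0.56, SE 0.10). Lower were the ribosomal RNA precursor RNA45S5 (log2 -1.76, SE 0.29), the keratin KRT6B (log2 -1.55, SE 0.29), which shares reads with its close relatives, TRHDE, which degrades thyrotropin-releasing hormone (log2 -1.51, SE 0.20; edgeR quasi-likelihood adjusted p = 0.00646), ATP8B4, a lipid flippase (log2 -1.35, SE 0.24), and SERTAD4 (log2 -1.28, SE 0.20). Each of these calls other than that of TRHDE ended when single libraries were left out, in 3 (SERTAD4) to 8 (PLEKHB1) of 8 cases, with adjusted p up to 0.148. The matrix protein THBS1 was at -1.01 (SE 0.20; edgeR quasi-likelihood adjusted p = 0.0512). In lists, no member passed over all genes: ribosomal proteins had a median of 0.22, with RPL5 at 0.28 (SE 0.11), NF-kB and cytokine genes -0.23, and dedifferentiation and S phase genes -0.16 each, which became 0.01 each on library size alone, when the median of all genes was 0.19. With single libraries left out these medians ran from 0.10 to 0.32 for ribosomal proteins, from -0.37 to -0.11 for NF-kB, from -0.22 to -0.13 for dedifferentiation and from -0.23 to 0.01 for S phase (0.01 without ketogenic replicate 1). Ketogenic replicates 1 and 4 stood apart in ribosomal proteins, with RPL5 at 619 and 638 CPM against 482 and 453 in the other 2 and 418 to 467 on the high fat diet. The list's median was 0.10 without the first and 0.13 without the fourth. Adjusted over the list alone, 1 dedifferentiation gene was higher and 3 were lower, and the other 3 lists had none. The 7 lists of other cell types had none past the test over all genes.

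The edgeR quasi-likelihood test passed 27 genes, 8 higher and 19 lower, against 2032 at an unadjusted p under 0.05. Camera gave ribosomal proteins (adjusted p = 0.00321), dedifferentiation (0.0145), S phase (0.0361) and NF-kB (0.0361), with adjusted p of 0.784 for dedifferentiation and 0.984 for the others with an estimated correlation, and 1 list without the second high fat library. A fit of only these 8 libraries and a fit with the ribosomal RNA share as a covariate passed 0 genes with edgeR, and with the covariate the median fold of the 27 genes went from 0.92 (SE 0.17) to 0.90 (SE 0.25). DESeq2 passed 330 and limma voom with quality weights 1057. Without the second, the third or the fourth high fat library edgeR passed 3, 4 and 3 genes, without the first, the third or the fourth ketogenic library 17, 6 and 47.

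The last comparison tested whether the inhibitor effect differed between the diets, as ketogenic minus high fat. The extremes given next are among genes past the test with a mean of at least 5 CPM in any group. LINC00663 (log2 3.41, SE 0.66), the membrane protein TMEM59L (log2 2.91, SE 0.50), BEST1 (log2 2.89, SE 0.56), LGI4, a secreted protein of nerve development (log2 2.88, SE 0.66), and the actin regulator WIPF3 (log2 2.84, SE 0.63) had the most positive differences. CYP24A1 (log2 -3.83, SE 1.05), the endothelial-type proteoglycan ESM1 (log2 -3.44, SE 0.81), the WNT antagonist DKK1 (log2 -3.17, SE 0.78), CORO1A (log2 -3.06, SE 0.49) and the transferrin receptor TFRC (log2 -3.04, SE 0.56) had the most negative. TFRC stood at 18.2 CPM in untreated high fat libraries, at 219 with inhibitors, and on the ketogenic diet at 104 and 153. In the same order DKK1 stood at 3.21, 26.9, 13.3 and 12.3 CPM. Leaving out single libraries ended the call of CYP24A1 in 9 of 16 cases (log2 -2.80 and adjusted p = 0.0874 without untreated ketogenic replicate 2), of DKK1 in 7 (up to 0.0641) and of ESM1 in 1 (0.0547). It moved BEST1 to 2.19 without untreated high fat replicate 4 and LINC00663 to 2.69 and WIPF3 to 2.23 without the first ketogenic library with inhibitors.

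Of 20 S phase genes 18 had a negative difference past the test (19 adjusted over the list alone), with a median of -1.44, among them E2F1 (log2 -1.91, SE 0.30), which stood at 11.4 CPM in untreated high fat libraries and at 38.2, 36.6 and 32.6 CPM in the other groups. CCNE2 (log2 -2.36, SE 0.42) and UHRF1, which maintains DNA methylation (log2 -2.18, SE 0.36), were also lowest in untreated high fat libraries, at 3.403 and 15.3 CPM. They were highest in high fat libraries with inhibitors, at 22.3 and 68.0 CPM, against 12.4 and 47.6 in untreated ketogenic libraries and 15.8 and 46.9 with inhibitors. Of 20 genes of G2 and mitosis 0 passed in edgeR, over all genes or over the list alone, with a median of -1.12 and CDK1 at -1.45 (SE 0.45). Without untreated high fat replicate 4, which lay far below its group in mitotic genes, the median was -0.80 and 6 were negative past the test. Ketogenic replicate 1 with inhibitors was also low (PLK1 at 44.4 CPM, others 79.2 to 128), and so were replicates 1 and 4 in TOP2A (161 and 184 CPM against 335 and 452). Without the first the median was -0.93 and without the fourth -1.09, with 0 past the test in each case. Glycolysis genes were negative in 5 of 21 (PKM -1.20, SE 0.26), genes of the unfolded protein response in 4 of 16 (PDIA4 -0.73, SE 0.19) and dedifferentiation genes in 5 of 20, with 1 positive (WNT5A -0.92 and CTGF -1.96 among the negative). Ribosomal proteins were positive in 4 of 24 (23 adjusted over the list alone), with a median of 0.61. Ketogenic replicates 1 and 4 with inhibitors stood apart here, with RPL10 at 1457 and 1618 CPM against 947 and 1030 in the other 2. Without the first the median was 0.50 and 0 were positive, and without the fourth 0.52 and 2. KDR (log2 -1.52, SE 0.32) and EPHA4 (log2 -1.47, SE 0.34) were negative, and DCT (log2 4.05, SE 0.89), AACS (log2 0.55, SE 0.16) and ACSL1 (log2 0.63, SE 0.16) positive. HSPB1 was at -0.82 and SERPINA1 at -1.09. Adjusted over the list alone, 10 glycolysis genes, 7 of the unfolded protein response and 8 of dedifferentiation (1 positive) were negative. Of the MAPK core 1 of 12 was negative over all genes, as were 1 of 19 YAP and TGF-beta targets, 1 of 19 handling genes and 0 of 26 of oxidative phosphorylation. Markers of leukocytes, of macrophages and of plasma had 1 negative member each and those of endothelium 2, those of fibroblasts had 1 positive, those of lung epithelium 2 and those of adipocytes 1 of each sign. With single libraries left out 8 to 20 S phase genes, 4 to 9 of glycolysis, 0 to 7 of the unfolded protein response, 3 to 8 of dedifferentiation and 0 to 5 of oxidative phosphorylation were negative over all genes. So were 0 to 3 of the MAPK core, 1 to 5 YAP and TGF-beta targets, 0 to 3 handling genes, 1 to 2 markers of endothelium and 1 to 2 of plasma. Without ketogenic replicate 4 with inhibitors 3 of the MAPK core, 5 YAP and TGF-beta targets and 3 handling genes were negative. Positive were 0 to 1 markers of fibroblasts, 1 to 2 of lung epithelium and 0 to 1 of adipocytes, and 0 to 1 of adipocytes were negative. Of ribosomal proteins 0 to 16 were positive. The calls of AACS, PDIA4, RPL5 and ACSL1 ended in 11, 8, 8 and 5 of the 16 cases (adjusted p up to 0.0932, 0.0741, 0.0683 and 0.0627) and that of HSPB1 in 1 (0.0513).

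**Figure D5:**
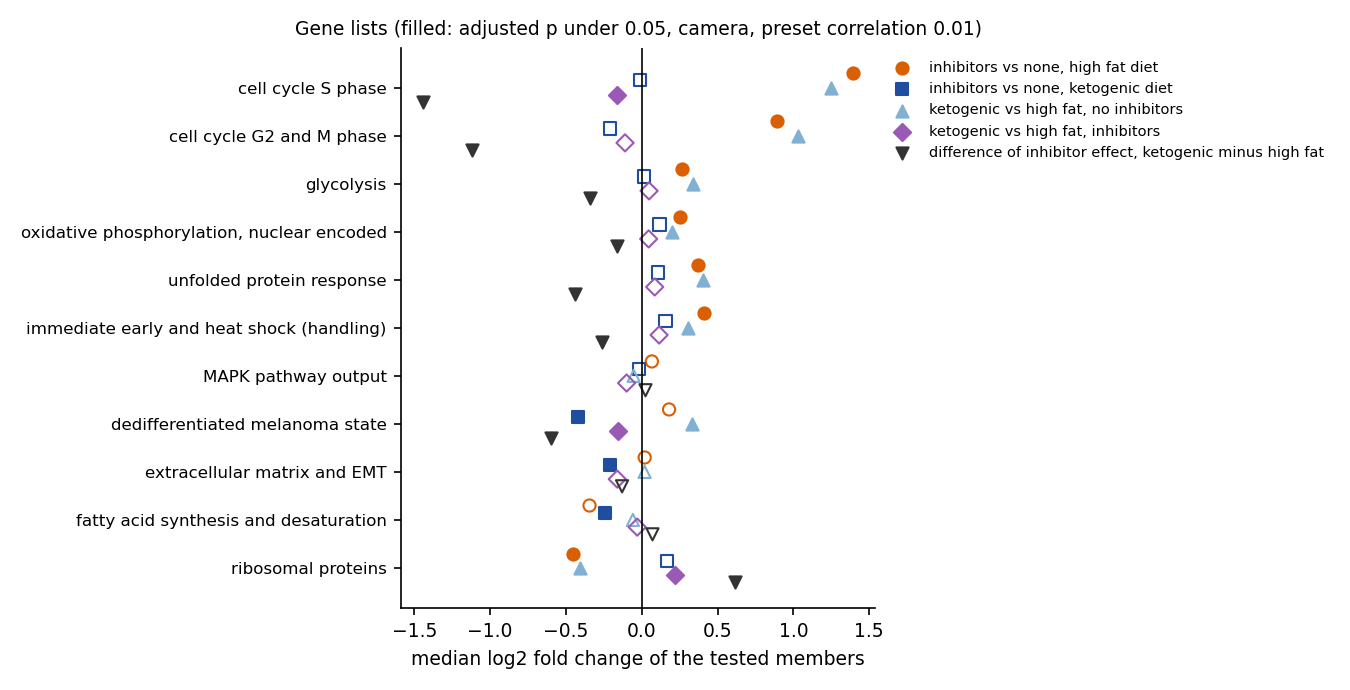
Median log2 fold change of the tested members of 11 gene lists in the 5 comparisons, filled where camera with its preset correlation gave an adjusted p under 0.05. With a correlation estimated per list none passed in any comparison. S phase genes lie at 1.39 for the inhibitors on the high fat diet and at 1.25 for the ketogenic diet without inhibitors. For the difference of effects they lie at -1.44. On library size alone the medians of matrix and fatty acid synthesis genes on the ketogenic diet change sign. So do those of dedifferentiation and S phase genes with inhibitors. That scaling counts ribosomal RNA and also moves the median of all genes up in both comparisons.

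The edgeR quasi-likelihood test passed 1444 genes, 698 positive and 746 negative, of which 1359 had also passed for the inhibitors on the high fat diet, against 4560 at an unadjusted p under 0.05. Camera passed 11 of 34 lists, and with an estimated correlation their adjusted p lay between 0.404 (dedifferentiation) and 0.755 (oxidative phosphorylation). With the ribosomal RNA share as a covariate 30 genes passed, and the median fold of the 1444 genes went from 0.89 (SE 0.22) to 0.83 (SE 0.26). Without the 3 libraries with over 30% ribosomal RNA 0 passed edgeR and the median fold was 0.86 (SE 0.27). With all libraries DESeq2 gave 2435 and limma voom with quality weights 5208. Single left-out libraries gave from 407 genes, without the second untreated ketogenic library, to 2636, without the fourth ketogenic library with inhibitors.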

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

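The tests of residual ribosomal RNA, of the 3 libraries richest in it, of liver and fibroblast RNA and of handling were chosen only after the results were seen, whereas those of other splits, of length and GC and of shared controls were written before their results were seen. The lists, the rule for named genes, the tests of the 5 comparisons and the first set of alternatives were chosen before the data were examined.

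More genes changed with inhibitors on the high fat diet (6771) than on the ketogenic diet (279), and the difference itself passed the test in 1444 genes. Residual ribosomal RNA as the cause of the larger count predicts a larger fall of its share on the high fat diet. Yet the log2 fall was 0.83 (SE 0.31) there and 1.74 (SE 0.35) on the ketogenic diet, larger by 0.90 (SE 0.46) where fewer genes changed. This order rests on the log2 scale. In percent the falls were of similar size, from 32.7 to 17.3 and from 23.7 to 7.08. Mean counts without ribosomal RNA rose from 40.8 to 47.2 M on the high fat diet and from 43.7 to 44.3 M on the ketogenic diet. The fall of the share thus does not decide on ribosomal RNA. With the share as a covariate 30 genes passed the test of the difference. The median log2 fold of the 1444 genes, with the median SE of the single genes, then went from 0.89 (SE 0.22) to 0.83 (SE 0.26). A part of ribosomal RNA in the difference thus stays open. With an offset for transcript length and GC content 1708 genes passed, which argues against those 2 properties. With all libraries 4560 genes had an unadjusted p under 0.05 in edgeR, and DESeq2 passed 2435 and limma 5208. Leaving out the 3 libraries richest in ribosomal RNA left 0 genes in edgeR. The other 23 sets of the same make-up left a median of 84 and at most 1777, and the 5 of them that also left 0 all held untreated high fat replicate 3, the library with most ribosomal RNA, and kept the fourth untreated library of each diet. Other sets that left out that replicate 3 left 15, 25 and 30 genes with the fourth high fat library also left out. With the fourth ketogenic library also left out they left 409, 751 and 973. The count thus depends on which libraries are left out together, and not on replicate 3 alone. The median fold of the 1444 genes went from 0.89 (SE 0.22) to 0.864 (SE 0.27) without the 3 libraries. These genes were selected with all libraries, most of which remain in that fit. A median that stays large is thus partly built in and does not decide on the 3 libraries as the source. Why the calls ended is not settled by fewer libraries alone. A true difference of the inhibitor effect between the diets may remain, and how far the untreated high fat libraries carry it is open.

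FMOD, FGL2 and TTR rose with inhibitors on both diets, by 3.90 to 5.49 on the log2 scale. Liver RNA would bring albumin and APOA1 far above TTR, yet the highest ratio of either to TTR in a library with inhibitors was 0.0348. Lung fibroblasts would bring COL1A1, yet COL1A1 changed by -0.45 (SE 0.37) CPM on the high fat and by -0.53 (SE 0.24) CPM on the ketogenic diet while FMOD rose by 5.24 and 10.7 CPM, a ratio of at most -0.0490. Other genes of fibroblasts rose on the high fat diet, COL3A1 by 2.97 (SE 1.21) CPM, DCN by 1.18 (SE 0.69), LUM by 0.90 (SE 0.43) and COL1A2 by 0.85 (SE 0.93), and on the ketogenic diet by 0.06 to 0.75 CPM. Each rose less than FMOD on both diets, and fibroblasts as a part of the rise on the high fat diet stay open. Mouse reads reach human gene models only in part, so both bounds hold for human-like sequence and a host source with another profile stays open. A change of the melanoma cells themselves is a candidate explanation and was not tested.

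Untreated ketogenic libraries differed from untreated high fat libraries in the direction that inhibitors moved high fat libraries: 1078 genes were higher in both comparisons where independent lists would share 263, 692 lower against 192, and 12 opposite. Both comparisons use the same untreated high fat libraries. Counts simulated gene by gene with no change, for these libraries as well, gave a covariance of 0.0533 and r of 0.502, beside 0.318 and 0.716 observed. Shifts of many genes together in a library were not part of that simulation. With those controls split between the comparisons, the mean covariance was 0.268 (0.241 to 0.285 over 6 assignments), so shared controls account for a small part. Handling common to the 4 untreated high fat libraries cannot be told apart from their group, and immediate early and heat shock genes, with a median of 0.303 between the untreated groups (0.58 without untreated high fat replicate 4), do not settle it. An effect of the ketogenic diet that resembles that of the inhibitors may also be present.

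Other splits of the libraries were counted for each result. For the gene counts only the real split of 35 reached 6771 genes on the high fat diet (highest other 15) and 279 on the ketogenic diet (highest other 130). The same held for 2163 between untreated diets (highest other 31) and 27 between treated diets (highest other 1). A share of 1 of 35 is the smallest that these splits can give, and it was not adjusted over the comparisons. It lies under 0.05 and so argues against chance for each of these counts without excluding it. For the difference of effects 2 of 100 splits gave as many as 1444 (highest other 1676), which does not decide on chance. The 96 that mix the untreated groups gave at most 1. Their counts say little, because the difference between those groups (2163 genes) then adds to the spread within groups. The 4 that keep each untreated group whole, the real one included, are too few for a share under 0.05. They gave 1444, 1676, 251 and 10 genes as treated libraries were regrouped, so the count also goes with the treated grouping. In the split with 1676 genes the 2 untreated groups were exchanged whole and the treated ones mixed. For the counts of lists chance cannot be excluded, with 20 of 35 splits reaching 8 lists (highest other 14), 34 of 35 reaching 3 (10), 11 of 35 reaching 12 (15), 31 of 35 reaching 4 (13) and 27 of 100 reaching 11 (14).

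Single libraries lay far from the other 3 of their group in 37 of 286 groups of 4 examined. For normal values chance flags about 1 in 20 groups, or 14.3. CPM need not be normal, genes of 1 library move together, and some genes were named after their values were seen. The 2 numbers are thus not a test. High fat replicate 1 with inhibitors had 52.0 M counts (M, mega) (others 58.1 to 59.2), 16638 genes with a count (18062 to 18225) and a second component score of 25.6 (-9.36 to -4.95). In CPM the same library had FMOD at 7.95 (4.21 to 4.79), BEST1 at 3.93 (2.25 to 2.51), WIPF3 at 3.13 (1.17 to 1.51) and DUSP6 at 510 (448 to 457). Replicate 4 without inhibitors on the high fat diet had STAC at 11.2 (6.34 to 6.78), EPHA2 at 71.5 (45.0 to 47.0), EDEM1 at 56.5 (31.9 to 35.3), S100A3 at 4.41 (1.44 to 1.80) and BEST1 at 47.5 (11.2 to 15.3). It also had TMEM59L at 72.3 (32.9 to 39.3), DKK1 at 6.46 (1.85 to 2.45), DUSP6 at 485 (212 to 249), AKR1C1 at 10.2 (24.4 to 26.4), IL1B at 21.9 (4.79 to 7.49), PLK1 at 7.07 (57.4 to 65.4) and TOP2A at 34.3 (261 to 297). In the same group FMOD was at 0.263 in replicate 3 (0.0875 to 0.108), and replicate 2 had E2F1 at 13.6 (10.5 to 10.8) and IGFBP5 at 16.5 (9.89 to 10.9). With inhibitors on the high fat diet CTGF was at 19.2 in replicate 2 (12.2 to 12.9) and RPL5 at 418 in replicate 4 (460 to 467). Untreated ketogenic replicate 2 had FADS1 at 144 (179 to 185), S100A3 at 43.1 (7.62 to 9.54), HSPB1 at 289 (230 to 238) and MX1 at 5.91 (7.61 to 7.71), and replicate 4 had BRAF at 17.1 (16.3 to 16.4). Ketogenic replicate 1 with inhibitors had a first component score of 0.44 (20.9 to 23.4), CORO1A at 2.55 (5.35 to 5.71), AKR1C1 at 13.1 (17.9 to 18.3) and MX1 at 26.8 (10.8 to 10.9). Replicate 3 of that group had a ribosomal RNA share of 4.10% (7.87 to 8.37) and CYP24A1 at 1.52 (0.139 to 0.293), and replicate 4 had SLC24A5 at 2.74 (5.40 to 5.93) and ESM1 at 4.57 (1.15 to 1.38).

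The inhibitor effect differed between the diets, by the edgeR test of the difference (ketogenic minus high fat), in 45 of the 94 genes named. Over all genes it did so in 1444 of 16012 (9.02%), and part of the 94 were named because they passed this test. Positive log2 differences were found for LINC00663 (3.41), STAC (2.04), FRAS1 (2.12), ZEB1 (0.83), BEST1 (2.89), C6orf48 (2.60), DCT (4.05), AACS (0.55), ACSL1 (0.63), RPL10 (0.75) and RPL5 (0.61). EIF3J-AS1 (1.24), LINC01138 (1.00), PCOLCE2 (1.18), KNOP1 (1.12), TMEM59L (2.91), LGI4 (2.88) and WIPF3 (2.84) were positive too. Negative differences were found for the cell cycle and metabolic genes CCNE2 (-2.36), E2F1 (-1.91), MCM5 (-1.87), UHRF1 (-2.18), SLC2A1 (-0.68), PKM (-1.20), LDHA (-0.86) and PDIA4 (-0.73). Signalling and matrix genes with negative differences were KDR (-1.52), F2RL1 (-1.26), EPHA4 (-1.47), CTGF (-1.96), NES (-0.79), THBS1 (-1.31), WNT5A (-0.92), DKK1 (-3.17), ESM1 (-3.44) and SERTAD4 (-1.14). SERPINA1 (-1.09), CYP24A1 (-3.83), CORO1A (-3.06), HSPB1 (-0.82), KRT6B (-2.36), TRHDE (-2.66), ATP8B4 (-1.63), TFRC (-3.04) and BCL2A1 (-0.998) complete the genes. By lists, the median difference was -0.29 for drug targets and MAPK core, -0.60 for dedifferentiation, -1.44 for S phase, -1.12 for G2 and mitosis, -0.34 for glycolysis, -0.16 for oxidative phosphorylation, -0.44 for the unfolded protein response and -0.42 for YAP and TGF-beta targets. It was 0.61 for ribosomal proteins, -0.26 for immediate early and heat shock genes and -2.12 for erythroid and plasma markers. With single libraries left out these medians ran from -0.64 to -0.16 for immediate early and heat shock genes, from -3.01 to -1.70 for erythroid and plasma markers and from -0.26 to -0.11 for oxidative phosphorylation. With an estimated correlation the adjusted p of these lists ranged from 0.404 to 0.755.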

How the results depend on the processing

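The settings on ribosomal RNA, on the 4 libraries least like their group and on length and GC were chosen only after the data were seen. Comparisons are named HF and K (inhibitors on the high fat and ketogenic diet), D0 and D1 (diets without and with inhibitors) and X (difference of effects), with 6771, 279, 2163, 27 and 1444 genes. RLE factors, the 1 CPM filter, no filter, removal of ribosomal RNA genes, and the length and GC offset kept each gene count within 1.5 times. The replicate numbers do not pair the libraries (r over 0.1 in 4 of 24 same-number pairs, and 3 of 16 libraries matched their own number best), and the replicate block gave 6826, 262, 2241, 21 and 1433 genes and moved no list count. Unless said otherwise the cause was not tested. A 1.5-fold minimum, a stricter test by construction, gave 1180, 19, 10, 0 and 1. Only the libraries compared gave 56 for K, 3346 for D0 and 0 for D1 in edgeR. In the edgeR fit of all libraries 2032 genes had an unadjusted p under 0.05 for D1. limma voom with quality weights gave 1456 for K, 6393 for D0, 1057 for D1 and 5208 for X, and DESeq2 850 for K, 330 for D1 and 2435 for X. Library size alone gave 981 for K (916 higher, 65 lower), 1 for D1 and 238 for X, and turned the split to 4856 higher and 1231 lower for HF and 1505 and 142 for D0. That scaling moved the median of all genes to 0.25 for HF, 0.28 for K, 0.15 for D0 and 0.19 for D1. It counts ribosomal RNA in the library size. The mean share of that RNA was lower with inhibitors in HF and K and on the ketogenic diet in D0 and D1. A lower share raises all other genes under this scaling, so such shifts arise without a change of those genes. The ribosomal RNA covariate gave 0 for K (2995 unadjusted in the edgeR fit without it), 0 for D1 and 30 for X. The median log2 fold of the K genes went from 0.86 (SE 0.18) to 0.83 (SE 0.32). The share did not overlap between the groups of K or of D1, so the lost calls there do not decide on ribosomal RNA. Without the 3 libraries over 30% ribosomal RNA the counts were 3858, 53, 0, 3 and 0 (4909 unadjusted for D0 and 4560 for X with all libraries), with the median fold of the D0 genes going from 0.62 (SE 0.15) to 0.58 (SE 0.21). Without the 4 least alike libraries K had 1029, D0 5271, D1 440 and X 3685. Leaving out each library gave 5446 to 6779 for HF, 88 to 437 for K, 778 to 2640 for D0, 3 to 47 for D1 and 407 to 2636 for X. Single libraries moved K to 88, 113 and 95 (untreated 1, 2, 4), 437 and 177 (inhibitors 1, 2), and D0 to 1044 (high fat 3) and 919, 778 and 1409 (ketogenic 1, 2, 3). They moved D1 to 3, 4 and 3 (high fat 2, 3, 4) and 17, 6 and 47 (ketogenic 1, 3, 4). X moved to 722 and 500 (untreated high fat 1, 3), 599, 684 and 566 (high fat with inhibitors 2, 3, 4), 455, 407 and 769 (untreated ketogenic 1, 2, 3) and 662 and 2636 (ketogenic with inhibitors 1, 4). List counts of 8, 3, 12, 4 and 11 became 0 in all 5 comparisons with an estimated correlation (camera, limma), fry gave 17 for HF, 5 for K and 1 for D1, no filter gave 5 for K, and single left-out libraries gave 5 to 8, 3 to 7, 11 to 16, 1 to 6 and 8 to 14. The correlation of the effects on both diets went from 0.389 to 0.168 without the low-count filter, which admits genes with few counts, and lay between 0.274 and 0.493 with single libraries left out. Among single genes 0 values reversed, where sign changes of genes that passed neither fit were not counted. Of all values of the named genes, 49 of 1142 for HF, 68 of 786 for K, 246 of 1275 for D0, 105 of 920 for D1 and 250 of 1708 for X no longer passed. These totals include named genes that did not pass in the main fit, so the share lost among genes that passed is larger. Depth limits genes such as FMOD, with 27 counts over the untreated high fat group, and SLC24A5, with 26 over the untreated ketogenic group.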

Other observations

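The lists in this part and their tests were fixed in advance. The genes named here were chosen only after their values were seen, with no hypothesis planned for them. Interferon-induced genes were among the few that rose on the ketogenic diet with inhibitors: IFIT3, which blocks viral translation together with its relatives, went from 15.3 to 27.9 CPM (log2 0.86, SE 0.15, n = 4 per group), IFIT2 from 9.11 to 14.4 CPM (log2 0.66, SE 0.15) and the antiviral GTPase MX1 from 7.23 to 14.9 CPM (log2 1.04, SE 0.25). On the high fat diet IFIT3 rose from 13.6 to 38.5 CPM. In all 3 of 22 interferon genes rose on the ketogenic diet, and 5 rose and 3 fell on the high fat diet, and the list passed camera on neither. With single libraries left out 1 to 3 rose on the ketogenic diet (1 without untreated replicate 1, 2 or 4). On the high fat diet 3 to 6 rose (3 without untreated replicate 2 or 3 or replicate 3 with inhibitors) and 1 to 3 fell (1 without untreated replicate 2 or without replicate 1 or 4 with inhibitors). The aldo-keto reductases AKR1C1 and AKR1C2, near-identical genes whose reads are hard to part, fell with inhibitors on the ketogenic diet by 1.02 (SE 0.23) and 1.37 (SE 0.25) and on the high fat diet by 0.77 (SE 0.23) and 1.01 (SE 0.25). On the ketogenic diet single left-out libraries ended the call of AKR1C1 in 7 of 8 cases, of IFIT2 in 5 and of MX1 in 4 (adjusted p up to 0.109, 0.118 and 0.120). Replicate 1 with inhibitors held 26.8 CPM of MX1 against 10.8 to 10.9 in the other 3, and without it MX1 was at 0.59. On the high fat diet they ended that of AKR1C1 in 1 (0.0502, without untreated replicate 1).

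On the high fat diet AREG, a ligand of the EGF receptor, went with inhibitors from 4.44 to 44.3 CPM (log2 3.31, SE 0.80), the cytokine IL1B from 10.1 to 42.7 CPM (log2 2.08, SE 0.61) and the chemokine CXCL8 from 86.3 to 199 CPM (log2 1.21, SE 0.42). On the ketogenic diet the same genes had log2 fold changes of 0.69 (SE 0.73), 1.68 (SE 0.60) and -0.23 (SE 0.41), none past the test. Without untreated high fat replicate 4 AREG was at 4.16 and IL1B at 2.81 on the high fat diet. The call of CXCL8 ended in 6 of 8 cases of single libraries left out (adjusted p up to 0.0933). In that comparison on the high fat diet, 4 of 18 genes of NF-kB and cytokines rose and 0 fell (0 rose adjusted over the list alone, and 1 with any of 5 libraries left out), p53 targets had 1 higher and 7 lower of 16, genes of the NRF2 response 5 and 4 of 21 and the amino acid response 2 and 1 of 20. In the same order there were, for apoptosis regulators 5 and 1 of 17, for antigen presentation 2 and 2 of 19, for hypoxia 3 and 1 of 16, for YAP and TGF-beta targets 5 and 2 of 19 and for drug efflux and detoxification 3 and 3 of 15, and none of these lists passed camera. Without untreated high fat replicate 4, 5 p53 targets rose and 3 fell, and 8 YAP and TGF-beta targets rose. With single libraries left out 0 to 2 YAP and TGF-beta targets fell, 0 to 5 p53 targets rose and 3 to 6 fell. Of NRF2 genes 2 to 6 fell (2 without untreated replicate 1 or 3), and of NF-kB genes 0 to 2 fell (2 without replicate 1 with inhibitors). Of the amino acid response 1 to 2 rose, of antigen presentation 1 to 2 fell and of drug efflux 1 to 3 rose.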
